A study of Mus musculus with 18 samples.

How the data were processed

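Bulk RNA sequencing of mouse colon organoids, which are epithelial cultures grown from the colon, was analysed in 18 libraries. The libraries form 6 groups of 3, one for each colon region (proximal, mid or distal) and medium. The control medium was ENR with Wnt3a-conditioned medium, in which the organoids proliferate, and the other medium was a differentiation medium, both applied 3 days after passaging per the labels. Each replicate is numbered 1 to 3 in every group, and the sources used here do not state whether the numbers stand for separate animals or for cultures of one animal. The p-values therefore measure only the spread between these samples. The RNA was poly-A selected, and the labels leave open whether the libraries kept the strand.

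The authors deposited one value per gene and library in FPKM, fragments scaled to gene length and library size, per the file headers, with a gene length in bases per the file headers. The submitters' processing notes name HISAT2 2.0.5 and featureCounts 1.5.0-p3 on the mm39 build, and the annotation release is not given in the sources used here. Multiplied by gene length, the values fell on whole multiples of a single step in every library for every gene, within a tolerance of 0.001 of a read, so the read counts behind the FPKM could be recovered. The summed reads and the library size behind the FPKM differed by a factor of 0.831 to 1.32, and how the authors scaled the libraries is not given in the sources used here. The table holds 56748 genes, 21970 of them protein-coding. It also holds 6 columns of group means made by the authors, which equal the mean of the 3 libraries and were not tested, and 0 value columns could not be mapped to a sample. Gene positions are those of the table on mm39, and no other annotation was used because the reference at hand is of another build.

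The recovered depth was 12827751 to 19938198 reads per library. A fold change against a group with 0 reads in all 3 libraries was computed against a floor of 3 reads over the group and is written as "at least", which covers counting error only.

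The comparisons, their tests, the gene lists and the rule for named genes were chosen before the data were examined, and exceptions are named where they are reported. Expression was analysed as log2(FPKM + 1), so fold changes between groups are understated for genes with low values. A difference in response between regions can be understated or overstated, since the fold at one end can be compressed more than at the other. Genes with an FPKM of at least 1 in at least 3 libraries were tested (12896 genes, 11034 of them protein-coding). One linear model with a mean for each of the 6 groups was fitted to all 18 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend, two-sided moderated tests, 12 residual degrees of freedom), and the Benjamini-Hochberg method adjusted the p-values over all tested genes within a comparison, with a threshold of 0.05. The comparisons were differentiation against control medium in each region, each pair of regions in each medium, the difference in medium response between distal and proximal organoids (an interaction term), and a moderated F test of any difference in medium response between the 3 regions. Errors beside fold changes are standard errors (SE) of the fit, and errors beside FPKM are standard deviations (SD) over the 3 libraries of a group. A pair of descriptions without a test was added. The first placed each mid library between the proximal mean (0) and the distal mean (1) over the genes called between distal and proximal with an absolute log2 fold change of at least 1. The second correlated fold changes across genes between comparisons that share no libraries, and genes are not independent replicates. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.

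In total 26 gene lists with 478 genes were tested with camera in limma where at least 5 members passed the filter, with a preset correlation of 0.01 between genes, Benjamini-Hochberg adjustment over the lists, and the estimated correlation beside it. The lists cover crypt stem and Wnt genes, proliferation, colonocyte, goblet, enteroendocrine and tuft cells, NAD and nicotinic acid metabolism, PPAR targets and fatty acid oxidation, oxidative phosphorylation, cholesterol synthesis, regenerative and fetal-like genes, interferon and MHC genes, antimicrobial defence, ion transport, xenobiotic metabolism, posterior Hox genes (paralogue groups 9 to 13), anterior and central Hox genes, proximal colon and distal colon markers, ER stress, immediate early genes, hypoxia and glycolysis, small intestine and Paneth cells, and fibroblast, immune and endothelial, neural or muscle cells. Some lists share members, such as Aqp8, which stands in the colonocyte, ion transport and distal colon lists. Named genes were fixed by rule. In the medium comparisons, distal against proximal in each medium and the interaction, the 6 highest and 6 lowest fold changes were taken among called protein-coding genes with a mean FPKM of at least 5 in one group and groups that do not overlap (not required for the interaction), leaving out predicted genes without a name. Up to 4 members of each list with the largest changes were added. The other comparisons took 3 and 3. Lgr5, Mki67, Krt20, Car1, Muc2, Hoxb13, Hoxd13, Osr2, Hcar2 and Naprt were always included. Some genes that the rule names are not reported here.

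Alternatives tried were a pseudocount of 0.1, no filter, a filter of FPKM 5, factors by the trimmed mean of M values (TMM) on the FPKM, a fit of only the groups compared, an added threshold of 1 on the log2 fold change, voom in limma on the recovered reads (genes with at least 10 reads in at least 3 libraries), the replicate number as a block, and leaving out each library in turn. Scaling each library to its summed reads was chosen after seeing the data. The same replicate numbers were checked for shared deviations from their group means across genes. The median correlation of same-number libraries was 0.107, with a range of -0.387 to 0.542. Of the 18 libraries 9 matched best with a library of their own number in another group, where 1 of the 3 libraries carries that number. In 2 of the 9 compared pairs of groups all same-number correlations were above 0.1. These were differentiation against control medium in distal organoids, at 0.118, 0.223 and 0.158, and distal against mid in control medium, at 0.177, 0.149 and 0.542. With the replicate block the calls in these 2 comparisons came to 8250 and 45, against 8110 and 42 without it.

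The procedure was tested on simulated data, with changes planted in 200 genes for the comparison of distal with proximal organoids in control medium. The filter left 12082 genes to test, and not all of the 200 were among them. At a true log2 fold change of 2 it recovered 49 of 50 genes (98%, median fitted 1.77) and at -2 it recovered 42 of 49 (85.71%, median fitted -1.58). At 1 it recovered 35 of 50 (70%, median fitted 0.89) and at -1 it recovered 31 of 49 (63.27%, median fitted -0.86). There were 11 false calls, 6.55% of the calls. In the interaction it recovered 28.28% of genes at a size of 1 and 76.77% at a size of 2. Of the 25 unchanged lists 0 were called. The simulated genes varied independently of each other, so this result does not cover lists whose genes are correlated. The planted genes were drawn only from genes above a minimum read count.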

Results

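Gene expression was measured by RNA sequencing in 18 libraries of mouse colon organoids from the proximal, mid and distal colon, each kept in a proliferative control medium or in a differentiation medium, with 3 libraries in each of the 6 groups. Recovered depth was 13090322 to 18504587 reads in the control libraries and 12827751 to 19938198 in the differentiation libraries. Protein-coding genes held 97.9% to 98.4% of the reads. Genes with an FPKM of at least 1 numbered 11250 to 11415 per control library and 10824 to 11244 per differentiation library. Mitochondrial genes took a larger share of reads in differentiation medium. The shares were 2.05% ± 0.0417 in proximal control and 2.57% ± 0.192 in proximal differentiation libraries, 2.50% ± 0.209 and 4.56% ± 0.346 in mid, and 2.67% ± 0.443 and 4.96% ± 0.851 in distal libraries (SD, n = 3). The 10 most abundant genes took 5.62% to 6.50% of reads in control and 7.43% to 11.8% in differentiation libraries. Replicates correlated at 0.953 to 0.990 across genes. The first principal component held 63.5% of the variance and separated the media, and proximal differentiation replicate 1 lay at 5.80 on it, nearer the control libraries than the other proximal differentiation libraries at 44.1 and 37.9.

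**Figure D1:**
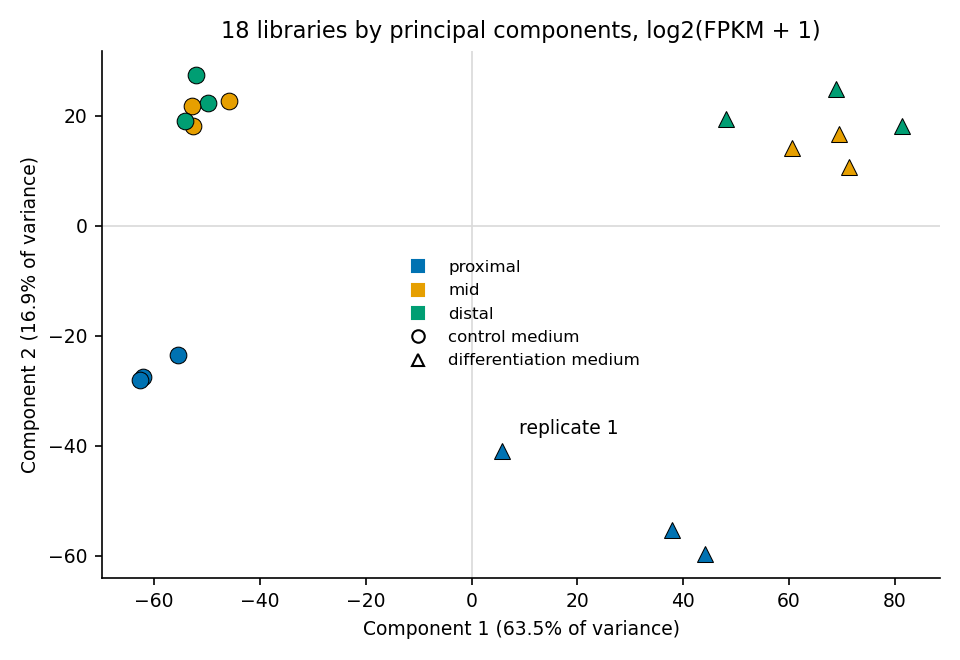
Each point is one of the 18 libraries on the first (63.5% of the variance) and second (16.9%) principal components of log2(FPKM + 1), coloured by region and shaped by medium. The media separate along the first axis, and proximal differentiation replicate 1, which is marked, lies at 5.80 on it.

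The comparison of differentiation with control medium asked which genes differ between the media in organoids of one region. In proximal organoids crypt genes were lower and colonocyte genes were higher in differentiation medium. Lgr5, a receptor of crypt base stem cells (ENSMUSG00000020140, chromosome 10, 115286216 to 115423685), fell from 3.10 ± 0.253 to 0.0235 ± 0.0407 FPKM (SD, n = 3; log2 fold change -2.002 ± 0.0995 SE, adjusted p = 3.47e-09, limma with Benjamini-Hochberg). Car1, a cytosolic carbonic anhydrase of colonocytes (ENSMUSG00000027556, chromosome 3, 14831276 to 14873428), rose from 596 ± 501 to 18982 ± 5676 FPKM (5.27 ± 0.42, adjusted p = 2.43e-07). Krt20, a keratin of differentiated surface cells (ENSMUSG00000035775, chromosome 11, 99319229 to 99328976), rose from 44.0 ± 11.4 to 696 ± 159 FPKM (3.96 ± 0.51, adjusted p = 2.02e-05). Naprt, which starts NAD synthesis from nicotinic acid (ENSMUSG00000022574, chromosome 15, 75762805 to 75766330), rose from 3.35 ± 0.932 to 27.8 ± 9.66 FPKM (2.698 ± 0.30, adjusted p = 4.67e-06).

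Beyond these, the largest rises in proximal organoids were those of Zg16, a lectin-like protein of goblet cell granules (7.02 ± 0.54), Tmigd1, an adhesion protein of enterocytes (6.44 ± 0.39), and Cyp2c55, a cytochrome P450 (6.34 ± 0.55). They were followed by Guca2a, the hormone guanylin (5.68 ± 0.31), Slc3a1, a subunit of an amino acid transporter (5.67 ± 0.51), and Dpep1, a dipeptidase (5.53 ± 0.47). Falls were ranked by fitted value among genes with a mean FPKM of at least 5 in one group, which leaves out Lgr5. The largest were those of Ccn2, a matricellular growth factor (-5.20 ± 0.58), Pmepa1, a target of TGF-beta signalling (-5.12 ± 0.44), and P2rx2, an ATP-gated channel (-4.88 ± 0.56). Next came Stra6, a receptor for retinol-binding protein (-4.78 ± 0.29), Fn1, fibronectin (-4.65 ± 0.91), and Gabrp, a GABA receptor subunit (-4.21 ± 0.39). Values after these gene names are log2 fold changes with SE over 3 libraries per group, and the adjusted p-values of the 12 genes ran from 9.6e-09 (Guca2a) to 0.00062 (Fn1). All 14 measured crypt stem and Wnt genes fell, and 14 fell when adjusted over the list alone (adjusted p = 8.88e-09). Among them were Sox9 (-4.08 ± 0.35), Axin2 (-3.10 ± 0.32), Cd44 (-3.06 ± 0.49) and Ascl2 (-2.68 ± 0.24). That list reached adjusted p = 0.128 with an estimated correlation. Of 20 proliferation genes 10 fell, 0 rose and 10 were not called, with 10 lower when adjusted over the list alone (adjusted p = 0.00272, adjusted p = 0.554 with an estimated correlation). The mean log2(FPKM + 1) of this list was 3.73 in proximal differentiation replicate 1, inside the proximal control range of 3.12 to 4.17, and 1.40 and 1.77 in replicates 2 and 3. Of 25 colonocyte genes 22 rose and 3 were not called, with 23 higher when adjusted over the list alone (adjusted p = 3.35e-10, adjusted p = 0.128 with an estimated correlation). Clca4b (4.65 ± 0.51) was among them, and reads of the Clca4, Cyp2c, Ces and Gsdmc families can be shared between their close paralogs. Goblet genes rose in 10 and fell in 3 of 17 cases, the same counts when adjusted over the list alone (adjusted p = 0.0251, adjusted p = 0.426 with an estimated correlation; adjusted p = 0.11 with a filter of FPKM 5). Among them were Muc2, the main gel-forming mucin, at 2.62 ± 0.36, Fcgbp at 4.54 ± 0.31 and Tff3 at 3.57 ± 0.36.

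PPAR targets and fatty acid oxidation genes rose in 18 and fell in 1 of 19 cases in proximal organoids, 18 and 1 when adjusted over the list alone (adjusted p = 6.92e-08, adjusted p = 0.128 with an estimated correlation). Among them were Ehhadh (2.11 ± 0.17) and Cpt1a, which admits fatty acids to mitochondria (1.80 ± 0.16). Cholesterol synthesis genes rose in 19 of 20 cases, 19 when adjusted over the list alone (adjusted p = 4.8e-08, adjusted p = 0.249 with an estimated correlation). Among them were Insig1, a sterol-regulated brake on the pathway, at 2.80 ± 0.36, Stard4 at 1.85 ± 0.26 and Cyp51 at 1.54 ± 0.22. Xenobiotic metabolism genes rose in 21 of 28 cases, 21 when adjusted over the list alone (adjusted p = 2.34e-09, adjusted p = 0.249 with an estimated correlation), with Ces2a, a carboxylesterase, at 5.44 ± 0.27. Oxidative phosphorylation genes rose in 18 of 24 cases, 21 when adjusted over the list alone (adjusted p = 2.2e-05, adjusted p = 0.426 with an estimated correlation), with Sdhb at 1.06 ± 0.18. Scaled to total reads, 12 of the 24 were called higher and 0 lower. NAD and nicotinic acid genes rose in 9 and fell in 2 of 15 cases, 9 and 2 when adjusted over the list alone, and the list did not pass (adjusted p = 0.0615). It passed with no filter (adjusted p = 0.00934), scaled to total reads (0.0199, with 7 higher and 4 lower) and without proximal differentiation replicate 2 (0.0464). Cd38, an enzyme that consumes NAD, rose by 2.697 ± 0.28, and Parp1, which also consumes NAD, changed by -1.46 ± 0.35. Regenerative and fetal-like genes fell in 14 of 19 cases, 14 when adjusted over the list alone (adjusted p = 7.6e-05, adjusted p = 0.420 with an estimated correlation). Among them were Spp1, osteopontin, at -3.59 ± 0.45 and Clu at -3.49 ± 0.66. Ion transport genes split, with 10 higher and 5 lower of 21, and 11 and 5 when adjusted over the list alone (adjusted p = 0.108; 0.0275 with no filter and 0.0088 scaled to total reads). Slc26a3, a chloride and bicarbonate exchanger, changed by 3.85 ± 0.63 and Kcnn4, a potassium channel, by -2.88 ± 0.21. Osr2, a transcription factor, rose from 10.5 ± 3.62 to 42.7 ± 4.99 FPKM (adjusted p = 3.22e-07). In all, 6938 genes were called in proximal organoids, 3565 higher and 3373 lower. Mki67, a marker of cycling cells, was 12.8 ± 5.65 and 5.10 ± 6.50 FPKM (-1.67 ± 0.59, adjusted p = 0.0267), and its call was lost without proximal control replicate 1 (adjusted p = 0.10), proximal differentiation replicate 2 (0.16) or proximal differentiation replicate 3 (0.0962).

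In mid organoids, crypt and proliferation genes were lower and colonocyte genes higher in differentiation medium. Aqp8, a water channel (ENSMUSG00000030762, chromosome 7, 123061514 to 123067227), rose from 18.4 ± 3.57 to 3078 ± 955 FPKM (SD, n = 3; log2 fold change 7.28 ± 0.32, adjusted p = 3.23e-10). Car4, a membrane-bound carbonic anhydrase (ENSMUSG00000000805, chromosome 11, 84848612 to 84856870), rose from 1.65 ± 0.971 to 347 ± 102 FPKM (7.05 ± 0.28, adjusted p = 1.19e-10). Lgr5 was at 4.61 ± 0.448 FPKM in control medium and at 0 reads in all 3 differentiation libraries, at least 751.89-fold lower. Mki67 (ENSMUSG00000031004, chromosome 7, 135291513 to 135318090) fell from 34.1 ± 3.90 to 2.24 ± 0.830 FPKM (-3.46 ± 0.59, adjusted p = 0.000127).

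The other largest rises in mid organoids were Ces2a (7.72 ± 0.27), Cyp4f14, a cytochrome P450 (6.88 ± 0.34), Prss30, a serine protease (6.54 ± 0.35), and Slc37a2, a sugar phosphate transporter (6.51 ± 0.41). Falls were ranked by fitted value among genes with a mean FPKM of at least 5 in one group, which leaves out Lgr5. The largest were Spp1 (-5.52 ± 0.45), Nox1, an NADPH oxidase of the colon epithelium (-4.97 ± 0.33), and Fn1 (-4.57 ± 0.91). Large falls were also those of Krt14, a basal keratin (-4.18 ± 0.46), Ccn2 (-4.14 ± 0.58) and Pmepa1 (-4.07 ± 0.44). All 14 crypt genes fell, 14 when adjusted over the list alone (adjusted p = 2.23e-07, adjusted p = 0.106 with an estimated correlation), with Ascl2, a transcription factor of stem cells, at -3.57 ± 0.24. All 20 proliferation genes fell, 20 when adjusted over the list alone (adjusted p = 1.2e-06, adjusted p = 0.386 with an estimated correlation), with the replication helicase gene Mcm3 at -3.71 ± 0.62 and Top2a at -3.62 ± 0.53. Colonocyte genes rose in 23 of 25 cases, 23 when adjusted over the list alone (adjusted p = 5.76e-11, adjusted p = 0.106 with an estimated correlation). In the NAD and nicotinic acid list 10 rose and 1 fell of 15, the same when adjusted over the list alone (adjusted p = 0.00615, adjusted p = 0.226 with an estimated correlation; adjusted p = 0.0645 with a filter of FPKM 5). It held Slc5a8, a sodium-coupled carrier of short-chain fatty acids and nicotinate (ENSMUSG00000020062, chromosome 10, 88721854 to 88765377), at 4.50 ± 0.34 and Naprt at 2.82 ± 0.30. Antimicrobial genes split into 6 higher and 2 lower of 12, 6 and 2 when adjusted over the list alone (adjusted p = 0.133; 0.0182 scaled to total reads). Tgm3, a transglutaminase, changed by 5.70 ± 0.34 and Saa1, an acute-phase protein, by 5.65 ± 0.50. Cholesterol synthesis genes went both ways, with 4 higher and 5 lower of 20, and 3 and 5 when adjusted over the list alone. The list had a median of -0.08, a mean of 0.06 and adjusted p = 0.920, and scaled to total reads 3 were higher and 12 lower. Among its members Insig1 changed by 1.57 ± 0.36 and Mvd by -0.90 ± 0.18. Ion transport genes rose in 12 and fell in 6 of 21 cases, 12 and 6 when adjusted over the list alone (adjusted p = 0.0458, adjusted p = 0.220 with an estimated correlation). That call was lost with a pseudocount of 0.1 (adjusted p = 0.075), a filter of FPKM 5 (0.0635), TMM factors (0.057) or only the groups compared (0.097). Enteroendocrine genes rose in 7 and fell in 1 of 10 cases, 7 and 1 when adjusted over the list alone (adjusted p = 0.0408, adjusted p = 0.226 with an estimated correlation), with the neuropeptide gene Tac1 at 2.69 ± 0.32. That list was not called, with adjusted p from 0.0521 to 0.0685, with a pseudocount of 0.1, a filter of FPKM 5, TMM factors or only the groups compared. In all, 8187 genes were called, 4065 higher and 4122 lower.

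In distal organoids Aqp8 rose from 10.1 ± 3.13 to 4090 ± 2012 FPKM (SD, n = 3; log2 fold change 8.46 ± 0.32, adjusted p = 6.49e-11) and Ces2a from 2.06 ± 0.560 to 889 ± 205 FPKM (8.17 ± 0.27, adjusted p = 3.2e-11). Krt20 rose from 29.6 ± 27.5 to 656 ± 167 (4.86 ± 0.51, adjusted p = 1.68e-06), and Muc2 (ENSMUSG00000025515, chromosome 7, 141276583 to 141308430) from 1.13 ± 0.639 to 20.3 ± 1.36 FPKM (3.36 ± 0.36, adjusted p = 1.83e-06). Spp1 fell from 163 ± 92.7 to 0.970 ± 1.41 FPKM (-6.42 ± 0.45, adjusted p = 3.44e-08). Other large rises were Car4 (7.11 ± 0.28), Cyp4f14 (7.10 ± 0.34), Cyp2c55 (6.92 ± 0.55) and Zg16 (6.71 ± 0.54). Other large falls were Ccn2 (-4.49 ± 0.58), Nox1 (-4.34 ± 0.33), Tnfrsf11b, osteoprotegerin (-4.30 ± 0.44), Fn1 (-4.24 ± 0.91) and Pmepa1 (-3.95 ± 0.44). All 14 crypt genes fell, 14 when adjusted over the list alone (adjusted p = 2.06e-07, adjusted p = 0.116 with an estimated correlation). Of 20 proliferation genes 19 fell, 19 when adjusted over the list alone (adjusted p = 3.52e-06, adjusted p = 0.349 with an estimated correlation). Colonocyte genes rose in 23 and fell in 1 of 25 cases, 23 and 1 when adjusted over the list alone (adjusted p = 2.02e-11, adjusted p = 0.116 with an estimated correlation). Goblet genes rose in 12 and fell in 2 of 17 cases, 12 and 2 when adjusted over the list alone (adjusted p = 0.00734, adjusted p = 0.349 with an estimated correlation). NAD and nicotinic acid genes rose in 10 and fell in 2 of 15 cases, 10 and 2 when adjusted over the list alone (adjusted p = 0.00944, adjusted p = 0.239 with an estimated correlation; adjusted p = 0.0632 with a filter of FPKM 5), with Slc5a8 at 4.02 ± 0.34 and Naprt at 2.85 ± 0.30. Oxidative phosphorylation genes rose in 23 of 24 cases, 23 when adjusted over the list alone (adjusted p = 4.63e-06, adjusted p = 0.349 with an estimated correlation), and scaled to total reads in 13 with 1 lower. The 20 cholesterol synthesis genes held 7 higher and 3 lower, 6 and 2 when adjusted over the list alone, with a median of -0.01, a mean of 0.26 and adjusted p = 0.513. Scaled to total reads, 3 of them were higher and 10 lower.

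Position genes moved with the medium in distal organoids too. Hoxb13 changed by 1.43 ± 0.17 and Hoxa13 by 1.36 ± 0.0872, while Hoxd13 changed by -1.28 ± 0.17 and Hoxa9 by -1.60 ± 0.17. Of the 8 posterior Hox genes 2 rose and 5 fell, 2 and 5 when adjusted over the list alone (adjusted p = 0.321; 0.0179 with no filter). In distal organoids 8110 genes were called, 4074 higher and 4036 lower. Across the regions 2597 genes were called higher and 2513 lower in all 3, and 55 were called in all 3 with unlike signs. Fold changes across genes correlated at 0.957 between mid and distal, 0.820 between proximal and distal and 0.808 between proximal and mid organoids. Between mid and distal organoids 3563 genes rose in both, against 1284 by chance, and 2 were called in opposite directions. Between proximal and distal organoids 2810 rose in both, against 1126 by chance, and 79 were called in opposite directions. Between proximal and mid organoids the counts were 2758, 1124 and 102. Scaled to summed reads, the median log2 fold change of all tested genes was -0.25, -0.33 and -0.34 in proximal, mid and distal organoids, against -0.01, 0 and 0.00302 before. The calls were then 2383 higher and 5177 lower in proximal, 2470 and 6005 in mid, and 2396 and 6106 in distal organoids.

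**Figure D2:**
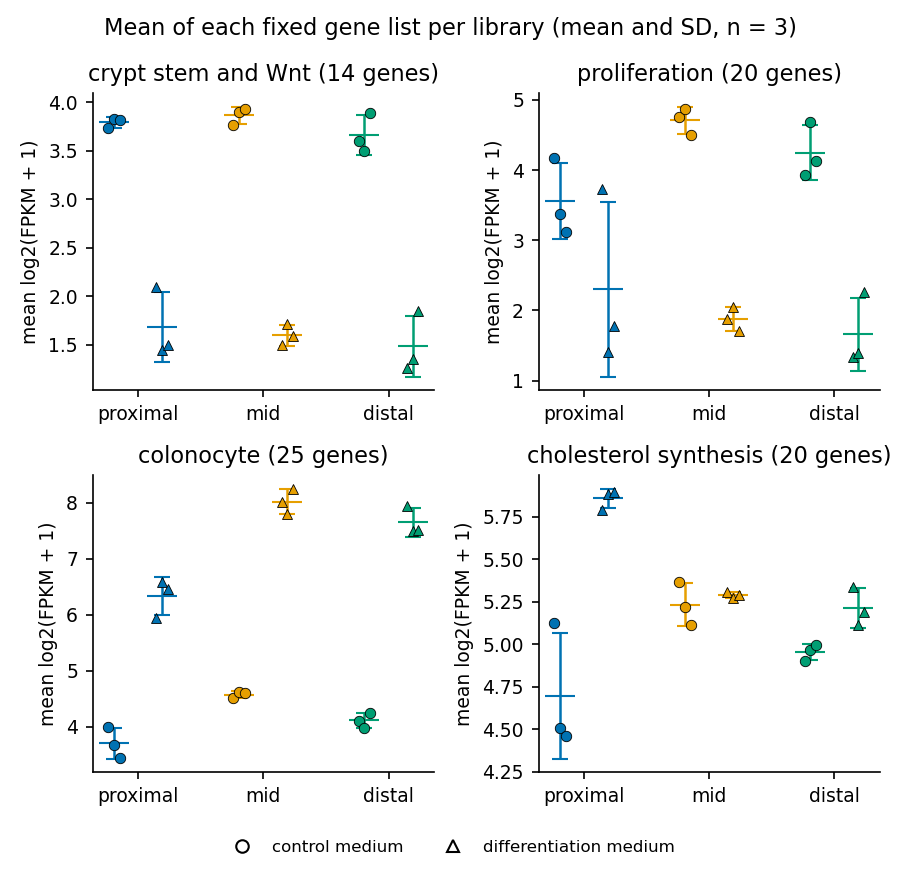
Mean log2(FPKM + 1) over the genes of 4 lists is shown for every library, by region and medium, with the mean and SD of each group (n = 3). On average, crypt stem and Wnt genes (14) and proliferation genes (20) are lower and colonocyte genes (25) higher in differentiation medium. Cholesterol synthesis genes (20) are higher in proximal organoids in differentiation medium. The proliferation mean of proximal differentiation replicate 1 (3.73) lies inside the range of the proximal control libraries (3.12 to 4.17).

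Distal and proximal organoids in control medium were compared to find which genes differ between regions in culture. The series title names colon regional identity as its subject. Hox genes and other position genes separated the ends of the colon. Hoxb13 (ENSMUSG00000049604, chromosome 11, 96085142 to 96088273) was at 65.9 ± 12.8 FPKM in distal organoids and at 0 reads in all 3 proximal libraries, at least 2611.5-fold higher in distal organoids (SD, n = 3; adjusted p = 1.26e-12). Hoxd13 (ENSMUSG00000001819, chromosome 2, 74498654 to 74501943) was at 57.9 ± 16.4 FPKM and at 0 reads in proximal libraries, at least 2583.8-fold higher (adjusted p = 1.26e-12). In the other direction Hoxb6 (ENSMUSG00000000690, chromosome 11, 96183302 to 96192395) was at 37.9 ± 7.08 FPKM in proximal and 0.196 ± 0.0463 in distal organoids (-5.01 ± 0.12, adjusted p = 2.26e-13). Osr2 (ENSMUSG00000022330, chromosome 15, 35296244 to 35303451) was at 10.5 ± 3.62 FPKM in proximal organoids and at 0 reads in all 3 distal libraries, at least 751.53-fold lower in distal organoids (adjusted p = 5.98e-10).

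Among other genes, Clic6, a chloride channel protein (4.77 ± 0.10), B3galt5, a glycosyltransferase (4.64 ± 0.29), Adh1, an alcohol dehydrogenase (4.64 ± 0.56), and Aldh1l1, an enzyme of folate metabolism (4.44 ± 0.21), were higher in distal than in proximal organoids. Tmem158 (-4.56 ± 0.31), Sptssb, a subunit of serine palmitoyltransferase (-4.13 ± 0.47), Nat8l, which makes N-acetylaspartate (-3.94 ± 0.41), Hoxb7 (-4.03 ± 0.0862) and Hoxb8 (-3.69 ± 0.13) were lower. Of 8 posterior Hox genes 7 were higher and 1 lower in distal organoids, 7 and 1 when adjusted over the list alone (adjusted p = 5.48e-15, and adjusted p = 0.000793 with an estimated correlation). Hoxa13 was at least 849.84-fold and Hoxa10 at least 1159.4-fold higher, and the lower one was Hoxb9. Of 12 anterior and central Hox genes 5 were higher and 6 lower, 5 and 6 when adjusted over the list alone (adjusted p = 0.00937, adjusted p = 0.344 with an estimated correlation; adjusted p = 0.112 with only the groups compared), and Hoxa7 was among the higher ones (2.82 ± 0.19). Neighbouring Hox genes overlap antisense transcripts, and without a stated strand their reads are not told apart. Distal colon markers were higher in 5 of 8 cases, 6 when adjusted over the list alone (adjusted p = 2.41e-11, and adjusted p = 0.000217 with an estimated correlation), with Aqp8 at 3.10 ± 0.32 and Tgm3 at 2.79 ± 0.34. Proximal colon markers did not move together, with 1 higher and 3 lower of 10, 2 and 3 when adjusted over the list alone, a median of 0.27, a mean of -0.07 and adjusted p = 0.417. Gsdmc4, a gasdermin, was higher in distal organoids (4.39 ± 0.62), and Fabp2, a fatty acid binding protein of enterocytes, was lower (-3.45 ± 0.29).

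Defence and secretory genes also differed between the ends. Antimicrobial genes were higher in distal organoids in 6 of 12 cases, 6 when adjusted over the list alone (adjusted p = 0.0002, adjusted p = 0.247 with an estimated correlation). Among them were Nox1 at 3.01 ± 0.33 and Lypd8, a secreted protein that binds bacteria, at 2.12 ± 0.36. Goblet genes were higher in 6 and lower in 1 of 17 cases, 9 and 3 when adjusted over the list alone (adjusted p = 0.00392, adjusted p = 0.502 with an estimated correlation). Among them were Spink4 at 2.38 ± 0.33, Klk1 at 1.80 ± 0.29 and Creb3l1 at 1.49 ± 0.26. Ion transport genes did not pass as a list, with 6 higher and 3 lower of 21, 9 and 4 when adjusted over the list alone (adjusted p = 0.0536). The list passed with a pseudocount of 0.1 (adjusted p = 0.0209), no filter (0.0386), TMM factors (0.0325) or scaled to total reads (0.0345), and without proximal control replicate 1 (0.0449) or distal control replicate 1 (0.0418). Its members included Aqp4 (2.73 ± 0.53), the proton pump gene Atp12a (2.67 ± 0.47) and Cftr, a chloride channel (-2.02 ± 0.39). Pyy, a hormone of enteroendocrine cells, was higher (2.46 ± 0.37). Regenerative and fetal-like genes were higher in 1 and lower in 4 of 19 cases, 1 and 4 when adjusted over the list alone (adjusted p = 0.00826, adjusted p = 0.667 with an estimated correlation). The higher one was Spp1 (3.49 ± 0.45), and Ereg, a growth factor (-1.99 ± 0.21), and Krt23 (-1.97 ± 0.28) were lower. That list was no longer called without distal control replicate 2 (adjusted p = 0.118). In the NAD list of 15 genes Cd38 was higher (1.01, adjusted p = 0.028) and Nmnat2 lower (-1.67 ± 0.28), 1 and 1 when adjusted over the list alone (adjusted p = 0.975). Cd38 was not called without distal control replicate 1 (adjusted p = 0.134) or 2 (0.0878), or proximal control replicate 2 (0.134) or 3 (0.128). Naprt was 4.60 ± 1.70 FPKM in distal and 3.35 ± 0.932 in proximal organoids (adjusted p = 0.545). Lgr5 (adjusted p = 0.809) and Mki67 (adjusted p = 0.394) were not called. Of 20 proliferation genes 0 were called, 0 when adjusted over the list alone, and the list was higher in distal organoids (median 0.81, adjusted p = 0.0120, adjusted p = 0.728 with an estimated correlation). That call was lost without distal control replicate 2 (adjusted p = 0.0928) or proximal control replicate 3 (0.0999). In all, 1360 genes were called, 718 higher and 642 lower in distal organoids, and without proximal control replicate 2 or 3 the calls came to 810 and 862.

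**Figure D3:**
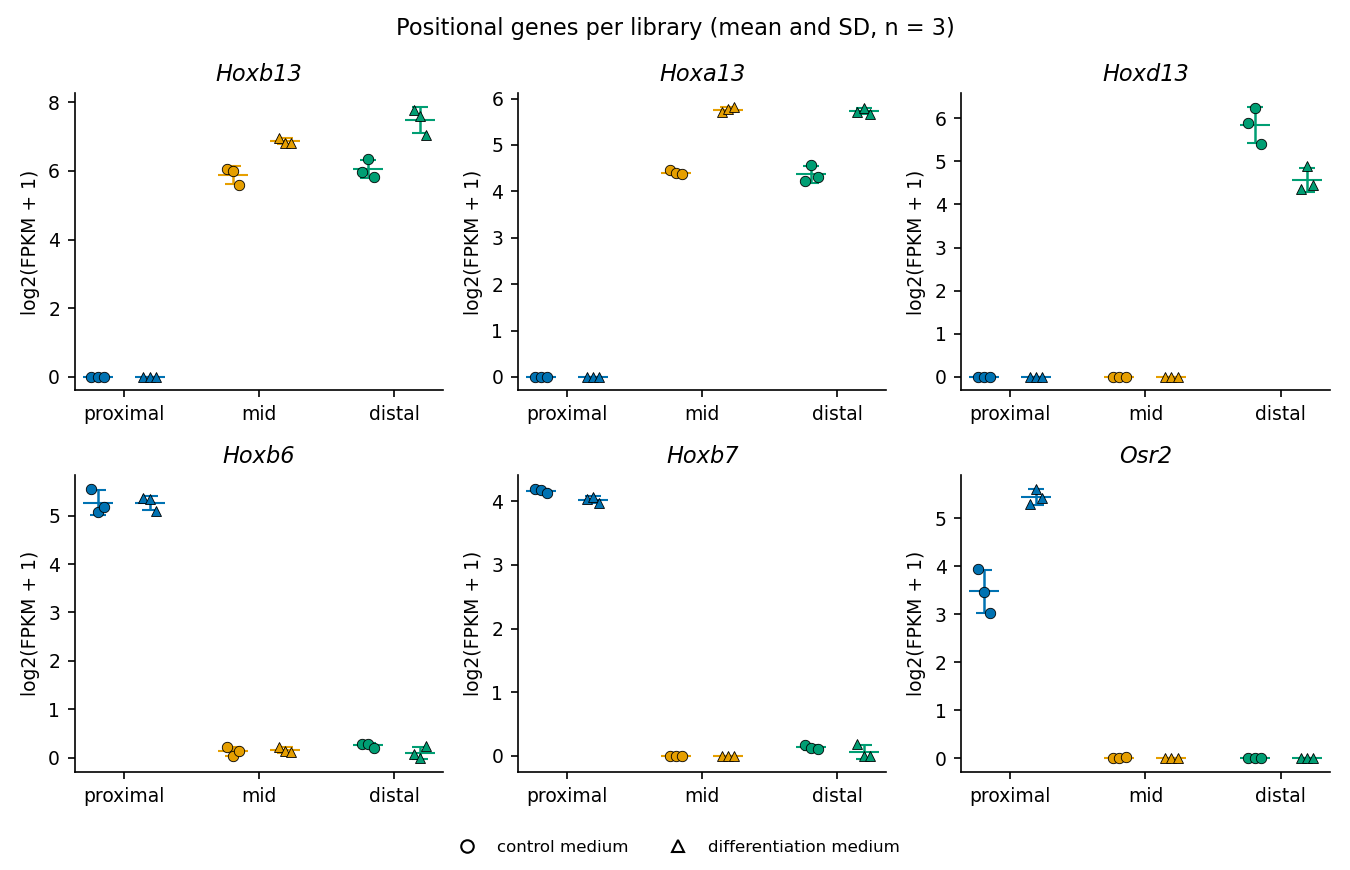
The log2(FPKM + 1) of Hoxb13, Hoxa13, Hoxd13, Hoxb6, Hoxb7 and Osr2 is plotted for every library, by region and medium, with the mean and SD of each group (n = 3). Hoxb13 and Hoxa13 are at 0 reads in proximal libraries, Hoxd13 is at 0 in proximal and mid libraries, and Hoxb6, Hoxb7 and Osr2 are near or at 0 in mid and distal libraries.

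In mid organoids in control medium goblet and enteroendocrine genes were higher than in proximal organoids, and position genes differed. Hoxb13 was at 58.5 ± 10.1 FPKM in mid and 0 reads in proximal libraries, at least 2319.9-fold higher in mid organoids (SD, n = 3; adjusted p = 2.29e-12). Adh1 (5.46 ± 0.56) and B3galt5 (4.71 ± 0.29) were also higher, and Hoxb6 (-5.13 ± 0.12) and Tmem158 (-4.18 ± 0.31) were lower. Hoxb7 was at 0 reads in all 3 mid libraries, at least 523.84-fold lower than in proximal organoids. Goblet genes were higher in 13 of 17 cases, 15 when adjusted over the list alone (adjusted p = 8.37e-11, and adjusted p = 0.0389 with an estimated correlation). Enteroendocrine genes were higher in 6 of 10 cases, 6 when adjusted over the list alone (adjusted p = 4.81e-05, and adjusted p = 0.0342 with an estimated correlation). Antimicrobial genes were higher in 8 of 12, 10 when adjusted over the list alone (adjusted p = 1.45e-07, and adjusted p = 0.0389 with an estimated correlation). In all, 1711 genes were called, 1030 higher and 681 lower. Without mid control replicate 1 the calls were 1006, without mid control replicate 2 they were 969, without proximal control replicate 2 they were 936, and without proximal control replicate 3 they were 921.

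Distal and mid organoids in control medium differed in few genes. Hoxd13 was at 57.9 ± 16.4 FPKM in distal and at 0 reads in all 3 mid libraries, at least 2885.4-fold higher in distal organoids (SD, n = 3; adjusted p = 7.42e-12). Rdx, radixin, which links membranes to actin (ENSMUSG00000032050, chromosome 9, 51958473 to 52011763), was at 16.2 ± 0.514 FPKM in distal and 1.39 ± 0.202 in mid organoids (2.85 ± 0.11, adjusted p = 3.27e-10). Goblet genes were lower in 2 of 17 cases, 11 when adjusted over the list alone (adjusted p = 1.23e-18, and adjusted p = 0.0304 with an estimated correlation). Enteroendocrine genes were lower in 0 of 10 cases, 5 when adjusted over the list alone (adjusted p = 6.56e-05, and adjusted p = 0.0435 with an estimated correlation). The posterior Hox list had a median of -0.10 with a mean of 0.76 and adjusted p = 0.0156, adjusted p = 0.241 with an estimated correlation. Apart from the estimated correlation, list tests of distal against mid and mid against proximal organoids, in either medium, were not repeated under the alternatives. Nor were they repeated with single libraries left out. In all, 42 genes were called, 18 higher and 24 lower. An unadjusted p under 0.05 was found for 716 of the 12896 tested genes, a share near the 0.05 expected by chance. With only the groups compared 5 were called, and with a filter of FPKM 5 there were 6. The count was 16, 21 and 17 without mid control replicate 1, 2 or 3, and 24, 14 and 69 without distal control replicate 1, 2 or 3.

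In differentiation medium distal and proximal organoids differed in colonocyte, position and cholesterol synthesis genes. Aqp8 was at 4090 ± 2012 FPKM in distal and 0.400 ± 0.208 in proximal organoids (SD, n = 3; 11.41 ± 0.32, adjusted p = 8.59e-13). Tgm3 was at 332 ± 116 and 0.0238 ± 0.0303 FPKM (8.29 ± 0.34, adjusted p = 6.34e-11), and Car4 at 235 ± 65.2 and 0.994 ± 0.625 FPKM (6.90 ± 0.28, adjusted p = 6.34e-11). Hoxb13, at 181 ± 44.8 FPKM, was at least 6244.6-fold higher in distal organoids, and Osr2, at 42.7 ± 4.99 FPKM in proximal organoids, was at least 2066.6-fold lower in distal ones, each against 0 reads in all 3 libraries of the other region. Car1 was not called, at 12775 ± 1632 in distal and 18982 ± 5676 FPKM in proximal organoids (-0.53 ± 0.42, adjusted p = 0.379).

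Other genes higher in distal organoids were Gsdmc4 (7.70 ± 0.62), Adh1 (7.57 ± 0.56) and Slc37a2 (7.55 ± 0.41). Gsdmc4 and Slc37a2 belong to the fixed list of proximal colon markers, yet were higher in distal organoids, whereas Osr2 of that list was lower. Lower ones were Hoxb6 (-5.16 ± 0.12), Cyp4b1, a cytochrome P450 (-4.99 ± 0.27), Sptssb (-4.84 ± 0.47), Prap1, a secreted gut protein (-4.76 ± 0.49), and Prl2a1, of the prolactin family (-4.71 ± 0.32). Colonocyte genes were higher in 14 and lower in 4 of 25 cases, 14 and 4 when adjusted over the list alone (adjusted p = 0.000552, adjusted p = 0.389 with an estimated correlation). The higher ones included Slc26a3 at 4.21 ± 0.63 and Slc20a1, a phosphate transporter, at 3.62 ± 0.16, and the 4 lower ones included Guca2a (-1.91), Guca2b (-3.30) and Tmigd1 (-2.90). Goblet genes were higher in 9 and lower in 1 of 17 cases, 10 and 1 when adjusted over the list alone (adjusted p = 0.00178, adjusted p = 0.389 with an estimated correlation). Enteroendocrine genes were higher in 5 and lower in 1 of 10 cases, 5 and 1 when adjusted over the list alone (adjusted p = 0.0254, adjusted p = 0.315 with an estimated correlation), with Tac1 at 3.52 ± 0.32 and Pyy at 2.80 ± 0.37. Ion transport genes were higher in 12 and lower in 4 of 21 cases, 13 and 4 when adjusted over the list alone (adjusted p = 0.00250, adjusted p = 0.0552 with an estimated correlation). Among them were Atp12a at 6.96 ± 0.47 and Hsd11b2, which inactivates glucocorticoids, at 3.10 ± 0.31. Oxidative phosphorylation genes were higher in 13 of 24 cases, 18 when adjusted over the list alone (adjusted p = 4.11e-06, adjusted p = 0.511 with an estimated correlation), with Ndufa1 at 1.14 ± 0.23. Mitochondrial genes took 4.96% ± 0.851 of reads in distal and 2.57% ± 0.192 in proximal libraries. Cholesterol synthesis genes were lower in 13 of 20 cases, 14 when adjusted over the list alone (adjusted p = 2.49e-06, adjusted p = 0.370 with an estimated correlation). Among them were Lss at -1.52 ± 0.21 and Cyp51 at -1.12 ± 0.22. Antimicrobial genes were higher in 7 and lower in 1 of 12 cases, 7 and 1 when adjusted over the list alone (adjusted p = 0.00117, adjusted p = 0.315 with an estimated correlation), with Saa1 at 5.45 ± 0.50.

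In the NAD and nicotinic acid list 4 genes were higher and 1 lower of 15 in distal organoids in differentiation medium, 4 and 1 when adjusted over the list alone (adjusted p = 0.108; 0.0276 without distal differentiation replicate 3). Slc5a8 was at 28.3 ± 16.6 and 3.85 ± 0.745 FPKM (2.46 ± 0.34, adjusted p = 6.17e-05), Nmnat3, a mitochondrial NAD-forming enzyme, at 3.003 ± 1.04 and 0.736 ± 0.0548 (1.17 ± 0.15, adjusted p = 3.27e-05), and Naprt at 40.6 ± 17.6 and 27.8 ± 9.66 (adjusted p = 0.227, not called). Nmnat2 was lower (-1.55 ± 0.28). Hcar2, a receptor for nicotinic acid, stayed under the filter, with at most 0.510 FPKM and 20 reads in a library. Posterior Hox genes were higher in 5 and lower in 1 of 8 cases, 7 and 1 when adjusted over the list alone (adjusted p = 8.98e-07, and adjusted p = 0.0249 with an estimated correlation). Distal colon markers were higher in 7 of 8, 7 when adjusted over the list alone (adjusted p = 2.01e-11, and adjusted p = 0.000183 with an estimated correlation), with B3galt5 at 5.45 ± 0.29. In all, 3856 genes were called, 2011 higher and 1845 lower. Scaled to total reads the median of all tested genes was -0.10, against 0 before, and the calls were 1429 higher and 2343 lower. Fold changes between distal and proximal organoids correlated at 0.608 across genes between the media, and 467 genes were higher and 389 lower in distal organoids in both media, against 112.0 and 91.8 by chance, with 19 called in opposite directions.

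Mid organoids in differentiation medium differed from proximal ones in ion transport, enteroendocrine and position genes. Aqp8 was at 3078 ± 955 in mid and 0.400 ± 0.208 FPKM in proximal organoids (SD, n = 3; 11.06 ± 0.32, adjusted p = 1.64e-12), and Tgm3 (8.27 ± 0.34) and Car4 (7.45 ± 0.28) were also higher. Osr2 was at least 2459.5-fold lower and Hoxb13 at least 3969.6-fold higher in mid organoids, and Hoxb6 (-5.11 ± 0.12) and Prap1 (-4.37 ± 0.49) were lower. Enteroendocrine genes were higher in 7 and lower in 1 of 10 cases, 8 and 1 when adjusted over the list alone (adjusted p = 0.000153, and adjusted p = 0.0455 with an estimated correlation). Ion transport genes were higher in 13 and lower in 4 of 21 cases, 13 and 4 when adjusted over the list alone (adjusted p = 0.00150, and adjusted p = 0.0455 with an estimated correlation). In all, 3786 genes were called, 2018 higher and 1768 lower, and scaled to total reads 1426 were higher and 2307 lower, with a median of -0.10 over all tested genes.

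Distal and mid organoids in differentiation medium again differed in few genes. Hoxd13, at 22.9 ± 4.85 FPKM, was at least 904.64-fold higher in distal organoids (SD, n = 3; adjusted p = 2.98e-10). S100g, a calcium-binding protein, was at 29.5 ± 15.6 in distal and 1.199 ± 0.857 FPKM in mid organoids (3.74 ± 0.44, adjusted p = 0.000522), and Rdx at 10.4 ± 1.19 and 0.784 ± 0.157 FPKM (2.68 ± 0.11, adjusted p = 8.28e-10). Sptssb (-3.82 ± 0.47), Fabp2 (-2.39 ± 0.29) and Chp2 (-2.29 ± 0.33) were lower. S100g, Sptssb and Fabp2 were not called with only the groups compared, nor Chp2 with a pseudocount of 0.1. Enteroendocrine genes were lower in 1 of 10 cases, 4 when adjusted over the list alone (adjusted p = 4.86e-05, and adjusted p = 0.0257 with an estimated correlation). In all, 89 genes were called, 27 higher and 62 lower, with 43 without mid differentiation replicate 1 and 59 without mid differentiation replicate 2.

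Mid organoids were placed between the ends over genes that differ between distal (1) and proximal (0) organoids. In control medium the mean place of the 3 mid libraries was 0.923 ± 0.0624 (SD, n = 3) over 616 genes, with single libraries at 0.989, 0.914 and 0.865. In differentiation medium it was 0.905 ± 0.0326 over 1259 genes, with 0.940, 0.876 and 0.898. In the control libraries 85.7% to 90.3% of these genes lay nearer the distal mean, and in the differentiation libraries 88.9% to 92.1%.

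The response to the medium was compared between the ends of the colon by an interaction term. Aqp8 rose by 8.46 on the log2 scale in distal organoids and was 0.276 ± 0.264 and 0.400 ± 0.208 FPKM in proximal ones, a difference in response of 8.31 ± 0.45, adjusted p = 4.81e-08 (SE, n = 3 per group). Slc20a1 went from 16.3 ± 2.84 to 123 ± 33.5 FPKM in distal and from 7.11 ± 0.661 to 8.84 ± 0.919 in proximal organoids (2.53 ± 0.22, adjusted p = 4.81e-06). In the other direction Guca2b, uroguanylin, went from 3.26 ± 1.48 to 42.9 ± 17.9 FPKM in proximal and from 2.86 ± 0.972 to 3.51 ± 1.92 in distal organoids (-3.19 ± 0.51, adjusted p = 0.00113). Cyp51, of cholesterol synthesis, went from 54.5 ± 25.2 to 151 ± 18.4 FPKM in proximal and from 70.9 ± 5.96 to 69.005 ± 10.4 in distal organoids (-1.58 ± 0.31, adjusted p = 0.00527). Naprt had no detectable difference in response (0.15 ± 0.42, adjusted p = 0.869).

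Positive differences (distal minus proximal) were those of Slc37a2 (6.31 ± 0.57), Car4 (6.16 ± 0.39), Tgm3 (5.50 ± 0.47), Slpi, a secreted protease inhibitor (4.72 ± 0.69), and S100g (4.45 ± 0.62). Negative ones were those of Cyp4b1 (-4.47 ± 0.38), Prl2a1 (-4.29 ± 0.45), Slc13a1, a sulfate transporter (-3.97 ± 0.33), and Slc51a, a bile acid exporter subunit (-3.77 ± 0.19). Cdo1, cysteine dioxygenase (-3.66 ± 0.42), and Trf, transferrin (-3.31 ± 0.23), which both fell in distal organoids, also had negative ones. Of these genes with Aqp8, 12 in all, voom on the recovered reads called 3, namely Aqp8, S100g and Trf. Cholesterol synthesis genes had a negative difference in 12 of 20 cases, 14 when adjusted over the list alone (adjusted p = 4.07e-11, adjusted p = 0.222 with an estimated correlation). Among them were Mvd at -1.68 ± 0.25, Lss at -1.62 ± 0.30 and Nsdhl at -1.37 ± 0.25. Colonocyte genes had a positive difference in 7 and a negative one in 4 of 25 cases, 7 and 4 when adjusted over the list alone (adjusted p = 0.000519, adjusted p = 0.755 with an estimated correlation). The positive ones were Car4, Aqp8, Ceacam1, Slc9a3, Slc5a8, Scnn1a and Slc20a1, and the negative ones included Car1, Guca2b and Tmigd1. Of these, Ceacam1 and Scnn1a were named after their values were seen. Voom did not call Car4 (adjusted p = 0.351) or Slc9a3 (0.67, adjusted p = 0.798), nor was Slc9a3 called with a pseudocount of 0.1 (0.391). Ceacam1 was not called without proximal differentiation replicate 1 (0.0718). Car1 was not called with no filter (0.267), with only the groups compared (0.104) or without distal control replicate 1 (0.068) or 2 (0.0527), proximal control replicate 2 (0.0826) or 3 (0.0744), proximal differentiation replicate 2 (0.0606) or 3 (0.0673), or distal differentiation replicate 2 (0.0708). Distal colon markers had a positive difference in 4 and a negative one in 1 of 8 cases, 5 and 1 when adjusted over the list alone (adjusted p = 0.000118, and adjusted p = 0.0158 with an estimated correlation). Proliferation genes fell in 19 of 20 cases in distal and 10 of 20 in proximal organoids. The difference was negative and called in 1, Cdk1, and in 0 when adjusted over the list alone (adjusted p = 0.000118, adjusted p = 0.801 with an estimated correlation). The list median was -1.34, and -0.68 without proximal differentiation replicate 1 (adjusted p = 0.032). In the NAD list Slc5a8 (2.53 ± 0.48, adjusted p = 0.00421) and Nmnat3 (1.29 ± 0.22, adjusted p = 0.00166) had positive differences, 2 of 15, 3 when adjusted over the list alone (adjusted p = 0.153; adjusted p = 0.0228 without distal differentiation replicate 3). Slc5a8 was not called with voom (2.93, adjusted p = 0.0734).

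In all, 1063 genes differed in response between the ends, 536 with a positive and 527 with a negative difference, and the F test over the 3 regions called 1237. Of the 1063, 315 were higher in differentiation medium at both ends with the larger rise in distal organoids and 122 with the larger rise in proximal organoids. A further 204 were lower at both ends with the larger fall in distal and 44 with the larger fall in proximal organoids, and 351 had opposite signs, 79 of them called at both ends. The remaining 27 had a response of 0 at one end. Without proximal control replicate 2 or 3, or distal differentiation replicate 2, the interaction called 617, 655 and 679 genes, and the F test called 689 and 702 without the first and the second of these. Scaled to total reads the median of all tested genes was -0.11, against -0.0065 before, and the interaction called 375 positive and 721 negative differences.

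**Figure D4:**
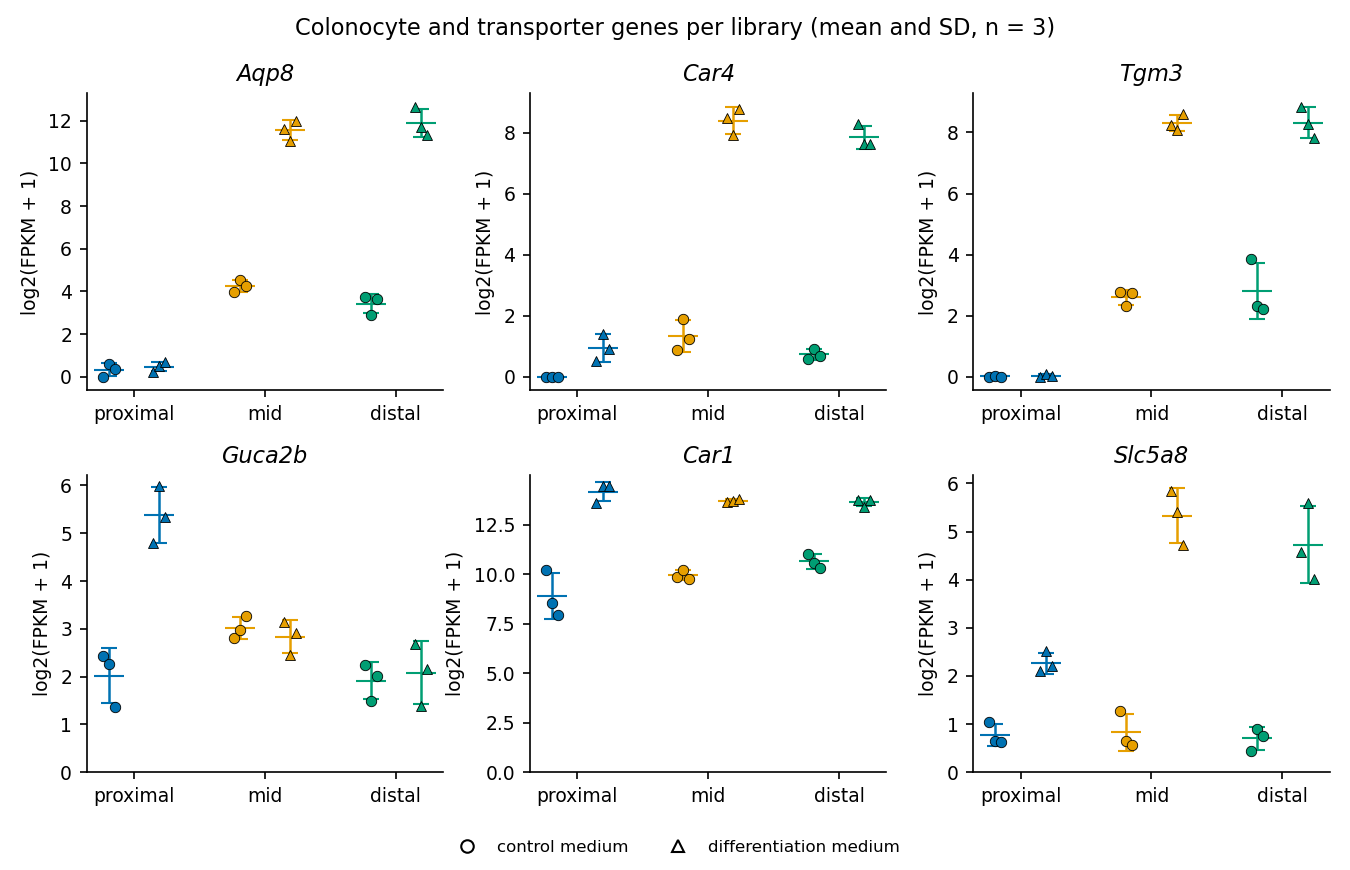
The log2(FPKM + 1) of Aqp8, Car4, Tgm3, Guca2b, Car1 and Slc5a8 is plotted for every library, by region and medium, with the mean and SD of each group (n = 3). Aqp8, Car4 and Tgm3 rise in mid and distal organoids and average under 1 FPKM in proximal ones, Guca2b rises in proximal organoids, and Car1 is higher in differentiation medium in all 3 regions.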

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

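The tests of the 3 patterns weighed below and the regroupings for the difference in medium response were chosen only after the results were seen, and these regroupings replaced a first form whose result had been seen. The splits of the libraries for the 9 pairwise comparisons were chosen before. The results in this part drew attention because the response to differentiation medium differed between distal and proximal organoids in a test of that difference, apart from one library that lay away from its group.

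Proximal differentiation replicate 1 lay nearer the control libraries on the first principal component than the others of its group. If control material had been mixed in, every gene that falls in differentiation medium would show the same share of control signal, yet the median share was 1.004 (median absolute deviation 0.310, 19 genes) for proliferation and 0.139 (0.0710, 12 genes) for crypt stem and Wnt genes, a difference of 0.865, and 0.384 (quartiles 0.178 to 0.552) over all 1147 genes at least 2-fold lower. Lower depth is argued against by its 15905639 recovered reads, more than replicate 2 of the group had (14365383). Continued proliferation in this library may explain the values, which was not tested, and no biological explanation was tested because the design gives none for a single library. Without it the proliferation list in the interaction had a median of -0.68 (adjusted p = 0.032), against -1.34 with it.

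In 7 colonocyte genes the medium response was larger in distal than in proximal organoids, and the list had a median difference of 0.70 (adjusted p = 0.000519, and adjusted p = 0.755 with an estimated correlation). A weak response of proximal differentiation replicate 1 alone is argued against, since 6 of the 7 were still called without it, with Ceacam1 lost (adjusted p = 0.0718). Less mature proximal organoids as a whole were taken to predict at most 1 colonocyte gene lower in distal than in proximal organoids in differentiation medium. There were 4, among them Guca2a (-1.91), Guca2b (-3.30) and Tmigd1 (-2.90), but more genes of the list were higher. On the first principal component the proximal differentiation libraries (5.80, 44.1 and 37.9) lay below every mid and distal one (48.1 or more). The rule was set after the values were seen, and a few genes cannot settle maturity, so this explanation stays open. The pseudocount, which compresses low starting levels, is argued against for the 4 genes that voom also called, Aqp8 (7.42), Ceacam1 (1.01), Scnn1a (1.69) and Slc20a1 (2.57). Voom did not call the other 3, and for Car4 (2.54) and Slc9a3 (0.67), 2 genes at under 0.5 times their value, the pseudocount and a regional difference cannot be told apart, whereas Slc5a8 had no smaller fold in voom (2.93 ± 0.89 SE, against 2.53), and region, which the design names, stays open as an untested explanation.

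Cholesterol synthesis genes rose in differentiation medium in proximal organoids, and their response was lower in distal ones, with a list median of -0.92 (adjusted p = 4.07e-11, and adjusted p = 0.222 with an estimated correlation). A single library as the cause is argued against, since the largest adjusted p was 5.32e-09 when each of 12 libraries was left out in turn (without distal differentiation replicate 3), with medians of -1.07 to -0.79. A lower starting level in proximal control organoids as the whole cause is argued against by 13 of 20 genes that were lower in distal organoids in differentiation medium, where the median was -0.66, against 0.33 in control medium. The median in control medium was 0.20 without proximal control replicate 2 (adjusted p = 0.181), 0.24 without proximal control replicate 3 (0.253) and 0.51 without proximal control replicate 1, and the list was not called without distal control replicate 3 (0.0864), with only the groups compared (0.0666) or with a filter of FPKM 5 (0.0571). Region, which the design names, stays open as an untested explanation.

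The interaction called 1063 genes. For the regroupings, the effects of region and medium were first taken out of each gene, and the values left were regrouped. Of 100 such regroupings of the 12 libraries 1, the real one, gave as many calls, with 787 as the highest other. The F test over the 3 regions called 1237. Of 100 such regroupings of the 18 libraries 1, the real one, gave as many calls, with 497 as the highest other. These regroupings argue against chance in each test but do not exclude it, since their smallest possible share is 1 of 100. The differences in log2 response (distal minus proximal) were 8.31 for Aqp8, 6.31 for Slc37a2, 6.16 for Car4, 5.50 for Tgm3, 4.72 for Slpi and 4.45 for S100g. They were -4.47 for Cyp4b1, -4.29 for Prl2a1, -3.97 for Slc13a1, -3.77 for Slc51a, -3.66 for Cdo1 and -3.31 for Trf. Of these 12 genes, each called with a pseudocount of 0.1 and without any single library, voom called Aqp8, S100g and Trf. Aqp8, Car4 and Tgm3 reached at most 0.606, 1.66 and 0.0579 FPKM in a proximal library, so their differences rest mainly on the distal response. Among colonocyte and NAD genes the differences were -3.19 for Guca2b, 2.53 for Slc20a1, 2.53 for Slc5a8, 2.06 for Slc9a3 and 1.29 for Nmnat3.

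In the cholesterol list the differences were -1.68 for Mvd, -1.62 for Lss, -1.58 for Cyp51 and -1.37 for Nsdhl. Position genes stood at -1.60 for Hoxa9, 1.43 for Hoxb13, 1.36 for Hoxa13, -1.28 for Hoxd13 and -1.96 for Osr2, and the values for Hoxb13, Hoxa13, Hoxd13 and Osr2 rest on one end of the colon alone, since the other end had 0 reads. Atp12a stood at 4.29, but at 2.21 with a pseudocount of 0.1 (adjusted p = 0.113) and, reversed, at -0.78 with voom (0.903), and Ly6g stood at 1.95. Car1 stood at -2.27 (adjusted p = 0.0294), and its call was lost with only the groups compared (adjusted p = 0.104) and with no filter (0.267). It was also lost without distal control replicate 1 (0.068) or 2 (0.0527), proximal control replicate 2 (0.0826) or 3 (0.0744), proximal differentiation replicate 2 (0.0606) or 3 (0.0673), or distal differentiation replicate 2 (0.0708). The proliferation list had a median difference of -1.34 (adjusted p = 0.000118, and adjusted p = 0.801 with an estimated correlation), and -0.68 without proximal differentiation replicate 1. The ion transport list had 0.50 (adjusted p = 0.0240, and adjusted p = 0.218 with an estimated correlation), and its call was lost with a pseudocount of 0.1 (adjusted p = 0.145), without proximal control replicate 1 (0.0588) and without distal differentiation replicate 1 (0.0538). Distal colon markers had a fitted median of 1.37, which is no bound because 2 members had 0 reads in proximal organoids (adjusted p = 0.000118, and adjusted p = 0.0158 with an estimated correlation).

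The 6 libraries of a pairwise comparison make 10 splits, which are too few for a share under 0.05. For differentiation against control medium 1 split, the real one, gave as many calls in each region, with 6938 calls and 1 as the highest other in proximal, 8187 and 0 in mid, and 8110 and 0 in distal organoids. In control medium distal against proximal gave 1360 calls with 81 as the highest other, and mid against proximal 1711 with 1 (1 split each). Distal against mid in control medium gave 42 calls in 2 of the 10 splits, the real one and another. The other split put the replicate 1 libraries together on one side and the replicate 3 libraries together on the other. Same-number libraries correlated at 0.177, 0.149 and 0.542 in this comparison, so a shared replicate effect could enter the count of the other split. With the replicate number as a block the real comparison did not call fewer genes, and the splits were not repeated with that block. In differentiation medium the values were 3856 and 796 for distal against proximal, 3786 and 1 for mid against proximal, and 89 and 5 for distal against mid (1 split each).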

How the results depend on the processing

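Scaling to summed reads was the only alternative chosen after seeing the data, and all other tests in this part were planned. A count is described as moved when it changed by more than 1.5 times, and except where stated the cause was not tested. The replicate block, TMM factors and scaling to summed reads moved none of the total counts of called genes. Scaling to summed reads did shift their direction. For the medium, 31.5%, 29.1% and 28.2% of calls in proximal, mid and distal organoids were then higher, against 51.4%, 49.7% and 50.2%. For distal against proximal in differentiation medium it was 37.9% against 52.2%. Summed reads over library size were 0.831 to 0.873 in control and 0.959 to 1.32 in differentiation libraries, so scaling and medium cannot be told apart. With a pseudocount of 0.1 distal against mid called 20 genes in control and 59 in differentiation medium, and the medium responses of mid and distal organoids correlated at 0.930. No filter gave 74 and 164 for distal against mid, and a filter of FPKM 5, which tests fewer genes, gave 6 and 56 with a correlation of 0.972. With only the groups compared, which leaves fewer libraries to estimate the spread, calls in control medium were 795 for distal against proximal and 5 for distal against mid. In differentiation medium they were 2020 and 7, and the interaction called 523. Requiring a log2 fold change of at least 1 as well, which can only lower a count, left 2336, 3480 and 3398 genes for the medium in proximal, mid and distal organoids. It left 616, 680 and 25 for distal against proximal, mid against proximal and distal against mid in control medium, 1259, 1193 and 51 in differentiation medium, and 579 in the interaction. Voom called 625 in the interaction.

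Leaving out each library in turn gave 810 to 1547 calls for distal against proximal, 921 to 1979 for mid against proximal and 14 to 69 for distal against mid in control medium. It gave 43 to 129 for distal against mid in differentiation medium, 617 to 1304 for the interaction and 689 to 1463 for the F test. The lowest values came without proximal control replicate 2 for distal against proximal, the interaction and the F test, proximal control replicate 3 for mid against proximal, and distal control replicate 2 and mid differentiation replicate 1 for distal against mid. The place of mid organoids ran from 0.792 to 0.958 in control and 0.813 to 0.918 in differentiation medium. The other counts stayed within 1.5 times, at 5605 to 7443, 7425 to 7675 and 7376 to 7985 for the medium in proximal, mid and distal organoids, and 2866 to 3944 for distal and 2860 to 3619 for mid against proximal in differentiation medium. In voom the interaction of Nox1 turned to 0.0302 and that of Atp12a to -0.78, and the cause was not tested. The proliferation list between distal and proximal organoids in differentiation medium turned from -0.66 to 0.10 without proximal differentiation replicate 1, in a range of -1.23 to 0.10 over the libraries left out. Of 9624 alternative values of named genes 9153 kept their direction and their side of the threshold, and in the medium comparisons, distal against proximal and the interaction so did 1725 of 1848 for lists. Of the 69 list calls in these 6 comparisons 5 were kept with an estimated correlation. They were posterior Hox genes and distal colon markers in distal against proximal organoids in both media, and distal colon markers in the interaction. Both lists hold Hoxb13 and Hoxd13. Another count model was planned only for a table of raw counts and was not run, since the table holds FPKM. Of the fits on read counts, only voom was run on the recovered reads. At the depth of 12827751 to 19938198 reads, genes without an FPKM of at least 1 in at least 3 libraries were not tested, and a group with 0 reads gives a bound only.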

Other observations

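No test in this part was chosen after its result was seen, apart from the scaling to summed reads. Further lists followed the medium. Hypoxia and glycolysis genes were higher in differentiation medium in 15 of 20 cases in proximal organoids, 16 when adjusted over the list alone (adjusted p = 0.000331, and adjusted p = 0.426 with an estimated correlation). They were higher in 8 cases in mid (adjusted p = 0.0507) and 10 in distal organoids (adjusted p = 0.0144, and adjusted p = 0.533 with an estimated correlation), with 0 lower, whereas scaled to total reads 4 were higher and 3 lower in mid and 7 and 2 in distal organoids. The mid list was called with no filter (adjusted p = 0.00878), the replicate block (0.0404), scaled to total reads (0.0435), only the groups compared (0.0182), and without mid control replicate 1 (0.0204) or mid differentiation replicate 2 (0.0457). The distal list was not called without distal differentiation replicate 1 (adjusted p = 0.0783) or with a filter of FPKM 5 (0.0616). In proximal organoids Ndrg1 changed by 2.10 ± 0.53, Egln3, an oxygen-sensing hydroxylase, by 2.03 ± 0.48, Pfkp by 1.82 ± 0.32 and Ldha, lactate dehydrogenase, by 1.55 ± 0.23 (log2 fold change with SE). Interferon and MHC genes were higher in 9, 13 and 9 and lower in 1, 1 and 1 of 19 cases in proximal, mid and distal organoids (adjusted p = 0.108, 0.00348 and 0.0317). The mid and distal lists reached adjusted p = 0.471 with an estimated correlation and adjusted p = 0.533 with an estimated correlation. The distal list was not called without distal differentiation replicate 1 (adjusted p = 0.0772), without distal control replicate 2 (0.0935) or with a filter of FPKM 5 (0.0861), nor the mid list with that filter (0.0635), and the proximal list was called when scaled to total reads (0.0228). Irf7, an interferon regulator, changed by 2.25 ± 0.46, 2.41 ± 0.46 and 2.11 ± 0.46, and H2-K1, a class I MHC chain, by 1.29 ± 0.19, 1.91 ± 0.19 and 1.66 ± 0.19. The lower gene was Bst2 in all 3 regions.

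Genes known from the small intestine and Paneth cells were higher in 5, 7 and 7 and lower in 2, 1 and 1 of 11 cases in proximal, mid and distal organoids (adjusted p = 0.0640, 0.0418 and 0.0171). The mid and distal lists reached adjusted p = 0.342 with an estimated correlation and adjusted p = 0.264 with an estimated correlation. The proximal list was called when scaled to total reads (adjusted p = 0.00535) and without proximal differentiation replicate 2 (0.045) or 3 (0.04). The mid list was not called with no filter (adjusted p = 0.077), a filter of FPKM 5 (0.089), TMM factors (0.0553), only the groups compared (0.097) or without mid control replicate 1 (0.0585), nor the distal list with a filter of FPKM 5 (0.0619). The retinol-binding protein gene Rbp2 changed by 3.67 ± 0.31, 5.38 ± 0.31 and 5.38 ± 0.31, and the bile acid carrier Slc10a2 by 4.19 ± 0.28, 3.30 ± 0.28 and 2.76 ± 0.28. Mmp7, a protease of Paneth cells, changed by -3.36 ± 0.36, -2.37 ± 0.36 and -1.81 ± 0.36. Proximal colon markers were higher in 6, 7 and 7 and lower in 1, 1 and 1 of 10 cases (adjusted p = 0.00375, 0.00348 and 0.00240), and with an estimated correlation the values were 0.249, 0.220 and 0.191. The lower one was Ang4, an angiogenin of the gut, and Slc37a2 stood at 6.27 ± 0.41 in distal and -0.04 ± 0.41 in proximal organoids.

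ER stress genes were higher in 4, 3 and 2 and lower in 2, 3 and 5 of 16 cases (adjusted p = 0.756, 0.938 and 0.419), and scaled to total reads higher in 2, 1 and 1 and lower in 6, 4 and 10. Among them were Asns at -1.78 ± 0.40 and Dnajb9 at 0.80 ± 0.17 in proximal organoids. Immediate early genes were higher in 3, 3 and 3 and lower in 4, 2 and 3 of 13 cases (adjusted p = 0.615, 0.790 and 0.899), and scaled to total reads higher in 2, 2 and 3 and lower in 7, 4 and 4. Among them were Ier3 at -1.92, -1.86 and -2.47 and Zfp36 at 1.21, 1.42 and 1.68. Scaled to total reads, the medians of the immediate early list in mid and distal organoids turned from 0.33 and 0.28 to -0.10 and -0.16, and that of the ER stress list in mid organoids from 0.00187 to -0.42.

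Of 14 tuft cell genes 1 passed the filter, Ptgs1, a cyclooxygenase, which changed by -1.43 ± 0.24, adjusted p = 0.000176 in proximal, -0.51 ± 0.24, adjusted p = 0.0721 in mid and -1.49 ± 0.24, adjusted p = 7.66e-05 in distal organoids. Of 13 fibroblast genes 2 were tested. Fn1 stood at 88.3, 125 and 122 FPKM in proximal, mid and distal control organoids, and Pdgfrb changed by 0.61 ± 0.37 (adjusted p = 0.174), 1.59 ± 0.37 and 2.28 ± 0.37 with the medium. Of the immune genes 2 were tested. Csf1r changed by -0.60 ± 0.17, -0.75 ± 0.17 and -1.07 ± 0.17, and Laptm5 was not called (adjusted p = 0.278, 0.0535 and 0.305). Of 12 endothelial, neural and muscle genes 0 passed the filter, with Pecam1 at most at 0.664 FPKM in a library. The fibroblast gene Vim and the immune gene Fcer1g, under the filter too, reached at most 1.24 and 1.004 FPKM.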
